A study of Mus musculus with 58 samples.

How the data were processed

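BMAL1 and CLOCK binding had been measured by ChIP-seq in dexamethasone-synchronised NIH3T3 cells and in mouse liver, and 4 deposited peak lists were analysed, 1 for each protein and context. Per the labels, the NIH3T3 BMAL1 list belonged to 7 libraries and the NIH3T3 CLOCK list to 6. The name of that BMAL1 list gave the time 20 h alone, so which libraries its peaks were called on is unclear. Per the series design text, the liver BMAL1 list was reprocessed by the authors from earlier libraries taken at zeitgeber time 6, and the liver CLOCK list belonged to a single sample, called pooled in its label. Bowtie, SAMtools, bedtools, STAR and FastQC and the genome build mm9 were named, without roles, per the submitters' processing notes. The peak caller, the thresholds, the tool versions and the filter of the NIH3T3 CLOCK list are not given in the sources used here.

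The deposited lists gave chromosome, start and end. The BMAL1 lists also gave a gene and the authors' signed distance in bp from the peak to its start site, and the NIH3T3 CLOCK list gave a gene. No list gave a score, a height or a value per library. The BMAL1 peaks were 5 to 100 bp wide with a median of 50, the NIH3T3 CLOCK peaks were all 50 bp wide and the liver CLOCK peaks all 250 bp. Because widths were set so differently, overlap was defined by the distance between peak centres. Starts are printed counting from 1. Depth per library and enrichment per peak are unknown from these lists, so precision was described by counts of peaks only. Of 345 gene symbols in the NIH3T3 BMAL1 list 330 matched a gene symbol or a unique synonym in a RefSeq table of assembly GRCm38.p6, as did 914 of 985 in the liver BMAL1 list and 605 of 670 in the NIH3T3 CLOCK list. That table was used for names and chromosomes only. A gene was missing for 6 NIH3T3 and 50 liver BMAL1 peaks. In the NIH3T3 CLOCK list the gene often lay on another chromosome than the peak, so that column was not used, and a CLOCK peak was linked to a gene through a BMAL1 peak within 500 bp. For CLOCK peaks found in both contexts the gene of the nearest BMAL1 peak was used at any distance.

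Peaks were called shared where centres lay within 500 bp, and peaks with no such partner in the other context were called liver-only or NIH3T3-only. The first 263 entries of both BMAL1 lists were identical, and how the authors assembled the lists is not given in the sources used here. Shares were given with 95% Clopper-Pearson intervals. As chance level, the first list was moved as a whole by 1000 random offsets of 10 kb to 1 Mb in either direction, which gave a one-sided permutation p with a smallest value of 0.001. This chance level was not used as evidence for the overlap of the BMAL1 lists, because identical entries fix its outcome. The shifts also move promoter peaks off promoters, so a low p cannot tell binding at the same sites from a common preference for promoters. Splits of a list were compared with two-sided Fisher exact tests and conditional odds ratios with exact 95% intervals. Promoter peaks were those within 1 kb of the authors' annotated start site. Gene lists were tested with two-sided Fisher exact tests over genes with at least 1 BMAL1 peak, with Benjamini-Hochberg adjustment over the 10 of 11 lists that had any such gene and a threshold of 0.05. Differences in odds ratios between contexts were given with percentile intervals from 5000 bootstrap draws of BMAL1 loci, on plain odds ratios with 0.5 added to each count. Peaks are not replicates, and none of these tests covers variation between cultures, animals or libraries.

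The comparisons, the gene lists, the rule for named genes and a first set of alternatives were chosen before the data were examined. That rule named all core clock and clock output genes with a peak and, for lists without scores, otherwise only genes of the fixed lists. A few genes that the rule covers are not reported here by name. The planned tests of peak scores, the stricter part of each list by score and the 10 highest peaks could not be run because the lists held no score. The alternatives in that set were overlap by at least 1 bp, centre distances of 200 and 1000 bp, shifts of 2 to 20 kb, promoter windows of 200 bp and 5 kb, genes within 10 kb and liver-only against NIH3T3-only genes. Joining peaks within 1 kb, leaving out clock genes and requiring identical intervals were chosen after seeing the data. On simulated data, with 50% of 463 NIH3T3 peaks planted at liver BMAL1 peaks in 50 draws, the overlap count was off by at most 1. The planted peaks lay inside the 500 bp limit, so this checked the counting alone. For the liver BMAL1 split of 1254 peaks, Fisher tests called 3.4% of 500 simulated splits without a difference and 98.8% of those with planted shares of 55% and 40%. The simulated peaks were independent, while the 1254 real peaks formed 1116 loci, so these rates do not cover grouped peaks. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9 were used. Sequence motifs at the peaks were not analysed here.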

Results

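BMAL1 (ARNTL) and CLOCK are the paired transcription factors that drive the activating arm of the mammalian circadian clock. The study asked how the sites and target genes of BMAL1 differ between a cell line and a tissue. The cell line was NIH3T3, a mouse embryonic fibroblast line whose cellular clocks were synchronised with dexamethasone, and the tissue was mouse liver. The 58 samples comprised 7 BMAL1 chromatin immunoprecipitation (ChIP-seq) libraries of NIH3T3 cells taken 12 to 38 h after dexamethasone and 6 CLOCK libraries of NIH3T3 cells taken at 18 to 38 h. A further 1 CLOCK sample, which its label calls pooled, came from liver, and 2 RNA polymerase II and 2 input libraries came from NIH3T3 cells. RNA was sequenced in 16 NIH3T3 libraries at 6 times and in 24 liver libraries at 12 times of day. The RNA, polymerase and input libraries were not analysed here. The values were the authors' 4 peak lists in mm9 coordinates, with 463 BMAL1 and 1016 CLOCK peaks in NIH3T3 cells and 1254 BMAL1 and 439 CLOCK peaks in liver. The liver BMAL1 list was the authors' reprocessing of earlier libraries taken at zeitgeber time 6. The lists held positions with no peak height or score and no values per library, so no replicate error could be given and the depth behind each peak is unknown. All intervals below cover counting error over peaks only, and the length of a list depends on depth and threshold, so list lengths were not compared as amounts of binding.

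The first comparison asked which BMAL1 sites the fibroblasts and the liver had in common. Of the 26 genes of the core clock list, 12 were annotated to a BMAL1 peak in either list, and 10 of these had a shared peak, namely Per1, Per2, Per3, Cry1, Cry2, Nr1d1, Nr1d2, Bhlhe40, Bhlhe41 and Gm129. Per and Cry genes encode the repressors of the clock, Nr1d1 and Nr1d2 encode the REV-ERB nuclear receptors, and Bhlhe40 and Bhlhe41 encode DEC1 and DEC2. Usp2, which encodes a deubiquitinase, had a peak in the liver list alone. Among the clock output genes that encode bZIP factors, Dbp, Tef and Hlf had shared peaks and Nfil3 had 2 peaks in the liver list alone. Over all genes, 274 of 463 NIH3T3 BMAL1 peaks (59.2%, 95% Clopper-Pearson interval 54.5 to 63.7) had a liver BMAL1 peak centre within 500 bp. In the other direction, 273 of 1254 liver peaks (21.8%, 19.5 to 24.2) had an NIH3T3 partner. The first 263 entries of both BMAL1 lists gave the same start and end. The lists therefore may not have been called independently, and both the overlap and the split into shared and single-context sites below may be set in part by how the authors assembled them, so no test of chance overlap is given for this pair of lists.

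Several clock genes carried groups of BMAL1 peaks near their start sites. The authors' distances can refer to different annotated start sites of the same gene. Nr1d1 had 7 peaks in NIH3T3 cells and 4 in liver. The nearest to the annotated start site, at 27 bp, was a shared peak at chromosome 11, 98636640 to 98636645, and a shared peak 8107 bp away lay at 98644729 to 98644778. Dbp, which encodes the D-box binding protein, had 6 peaks in NIH3T3 cells and 4 in liver, and shared peaks lay at chromosome 7, 52960316 to 52960364 and at 52963122 to 52963171. Their distances of 119 bp and 113 bp refer to different start sites. Tef had 4 peaks in each context, each within 149 bp of an annotated start site, though not of the same one, between 81641371 and 81641787 on chromosome 15. The Per1 peak nearest to its start site covered chromosome 11, 68908641 to 68908699, at 50 bp. For Per2 the nearest peak covered chromosome 1, 93355864 to 93355925, at 11 bp, and for Cry1 it covered chromosome 10, 84647758 to 84647807, at 17 bp. Each of these 3 peaks was in both BMAL1 lists. Hlf combined a shared peak 27255 bp from the start site (chromosome 11, 90279441 to 90279533) with an NIH3T3-only peak at 31 bp and 3 liver-only peaks.

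**Figure D1:**
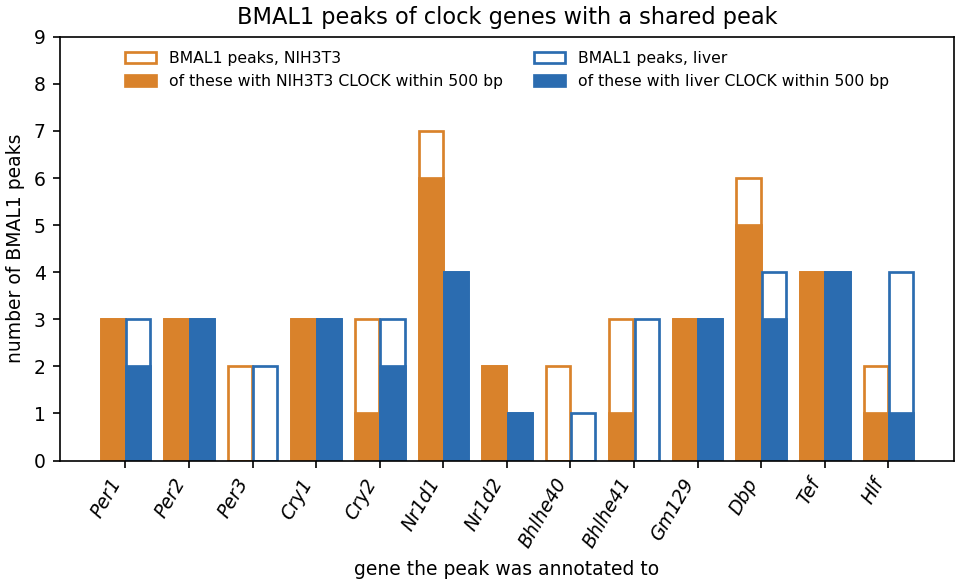
Number of BMAL1 peaks (vertical axis) annotated to each core clock and clock output gene with a shared peak (horizontal axis) in NIH3T3 cells (orange) and liver (blue), with the filled part marking peaks that had a CLOCK peak of the same context within 500 bp. Nr1d1 has 7 peaks in NIH3T3 cells and 4 in liver, and Per3 and Bhlhe40 have no CLOCK peak at their BMAL1 peaks in either context.

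The second comparison set the position of shared sites against that of sites found in a single context. Shared BMAL1 sites lay at promoters, as at Per1, Per2 and Cry1, while most liver-only sites lay farther away. Liver-only peaks of metabolic genes included those of Fabp1 (fatty acid binding) at 26924 bp and Apoa5 (plasma triglyceride control) at 7360 bp. Others were close to the start site, such as those of Plin2 (lipid droplet coat) at 3 bp, Elovl6 (fatty acid elongation) at 7 bp and Ldha (lactate dehydrogenase) at 94 bp. In liver, 230 of 273 shared peaks (84.2%, 79.4 to 88.4) and 330 of 981 liver-only peaks (33.6%, 30.7 to 36.7) lay within 1 kb of the annotated start site. The odds ratio was 10.5 (95% interval 7.36 to 15.3; two-sided Fisher exact p = 2.36e-52). In NIH3T3 cells, 230 of 274 shared peaks (83.9%, 79.1 to 88.1) and 102 of 189 NIH3T3-only peaks (54.0%, 46.6 to 61.2) did so, an odds ratio of 4.44 (2.84 to 7.04; two-sided Fisher exact p = 3.65e-12). Most shared peaks were the same entries in both lists, so the tests in liver and in NIH3T3 cells are not independent results. With promoters limited to 200 bp the odds ratios were 5.18 in liver and 2.02 in NIH3T3 cells. The median distance was 179 bp for shared liver peaks, 585 bp for NIH3T3-only peaks and 6140 bp for liver-only peaks. NIH3T3-only peaks were at promoters more often than liver-only peaks, with an odds ratio of 2.31 (1.67 to 3.21; two-sided Fisher exact p = 2.61e-07). This last test was not among the comparisons chosen in advance.

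**Figure D2:**
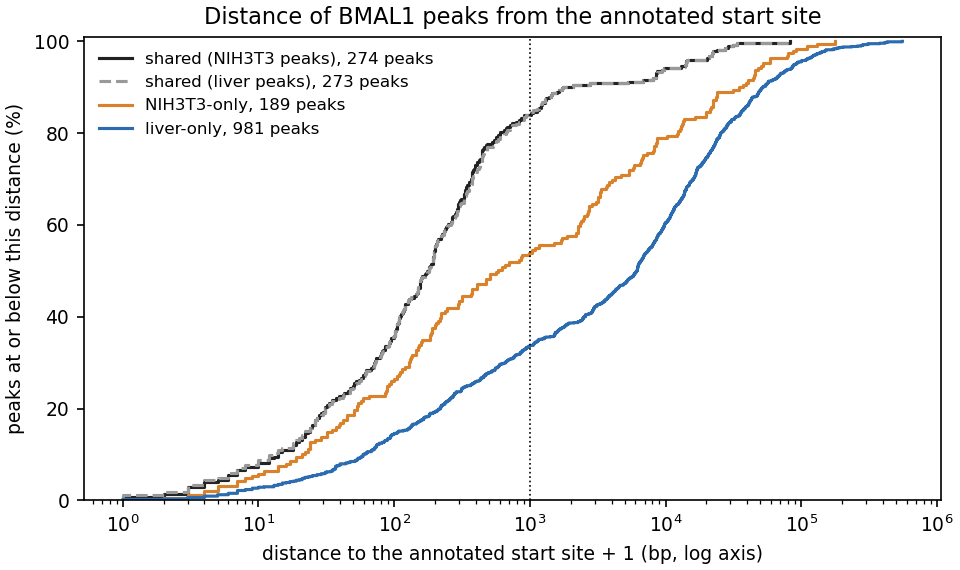
Cumulative percent of BMAL1 peaks (vertical axis) by distance to the annotated start site plus 1 bp (horizontal log axis), for shared peaks of each list (black and grey), 189 NIH3T3-only peaks (orange) and 981 liver-only peaks (blue). At the dotted line at 1 kb the shared curves stand at 83.9% and 84.2%, the NIH3T3-only curve at 54.0% and the liver-only curve at 33.6%.

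The third comparison asked where CLOCK, the partner of BMAL1, had peaks at BMAL1 sites. A single CLOCK peak can lie within 500 bp of several BMAL1 peaks and was then counted at each of them. In NIH3T3 cells every BMAL1 peak of Per1, Per2, Cry1, Nr1d2, Gm129 and Tef had a CLOCK peak within 500 bp, as did 6 of 7 peaks of Nr1d1 and 5 of 6 of Dbp. CLOCK stood at 1 of 3 peaks of Cry2, 1 of 3 of Bhlhe41 and 1 of 2 of Hlf, and at none of Per3 and Bhlhe40. Outside the clock, NIH3T3 CLOCK peaks stood at all 3 NIH3T3 peaks of Wee1 (a kinase that holds back mitosis), both of Pcx (pyruvate carboxylase), both of Tsc22d3 (a glucocorticoid-induced factor) and at those of Foxo3, Hif1a and Tcf7l2. The peaks of Tsc22d3, at 22275 and 31415 bp, and of Tcf7l2, at 131057 bp, lay far from the annotated start sites. Over all sites, 102 of 463 NIH3T3 BMAL1 peaks (22.0%, 18.3 to 26.1) had an NIH3T3 CLOCK peak, against a mean of 0.336 and a maximum of 6 after the shifts (one-sided permutation p = 0.001, the smallest these shifts can give). As the shifts move promoter peaks off promoters, this and the shift tests below do not separate joint binding from a common preference for promoters. When the intervals had to overlap by at least 1 bp, the share was 12.5%.

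In liver, CLOCK peaks stood at all BMAL1 peaks of Per2, Cry1, Nr1d1, Nr1d2, Gm129 and Tef, at 2 of 3 of Per1 and of Cry2, at 3 of 4 of Dbp and at 1 of 4 of Hlf. The liver peaks of Per3, Bhlhe40, Bhlhe41, Usp2 and Nfil3 had none. The 2 Cry2 peaks with liver CLOCK were overlapping entries at 1 site, 8513 bp from the start site. In NIH3T3 cells CLOCK stood instead at the Cry2 peak at 192 bp. No member of the lipid, glucose, xenobiotic, cell cycle, fibroblast, hepatocyte or stress lists had a liver CLOCK peak at a liver BMAL1 peak. In the list of other transcription factors, Klf13, a Krüppel-like factor, was the single such gene, at chromosome 7, 71062757 to 71062806. Over all sites, 54 of 1254 liver BMAL1 peaks (4.31%, 3.25 to 5.58) had a liver CLOCK peak, against a mean of 0.217 and a maximum of 3 after the shifts (one-sided permutation p = 0.001). Without peaks annotated to core clock and clock output genes the share was 2.23%. The longer NIH3T3 CLOCK list stood at more of the same liver BMAL1 peaks, 82 of 1254 (6.54%, 5.23 to 8.05). A liver BMAL1 peak without a liver CLOCK peak was therefore not read as a site without CLOCK. The liver CLOCK list came from a single sample that its label calls pooled. No time was given for that sample, while the liver BMAL1 libraries were taken at zeitgeber time 6, so the lists may differ in time.

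BMAL1 sites shared by both contexts had CLOCK peaks more often than sites of a single context. In liver, CLOCK stood at 39 of 273 shared peaks (14.3%, 10.4 to 19.0) and 15 of 981 liver-only peaks (1.53%, 0.858 to 2.51), an odds ratio of 10.7 (5.66 to 21.3; two-sided Fisher exact p = 5.93e-16). In NIH3T3 cells, CLOCK stood at 78 of 274 shared peaks (28.5%, 23.2 to 34.2) and 24 of 189 NIH3T3-only peaks (12.7%, 8.31 to 18.3), an odds ratio of 2.73 (1.62 to 4.73; two-sided Fisher exact p = 5.70e-05). Genes of the clock lists contributed much of the difference. Without their peaks the odds ratio was 3.96 in liver (1.69 to 9.21; two-sided Fisher exact p = 6.84e-04) and 1.76 in NIH3T3 cells, where the interval reached below 1 (0.997 to 3.17; two-sided Fisher exact p = 0.0475). These tests treat peaks as independent, although peaks of genes such as Nr1d1 stand close together. When BMAL1 peaks closer than 1 kb were joined into loci, the odds ratios were 8.22 in liver (4.02 to 17.3) and 2.46 in NIH3T3 cells (1.37 to 4.55). None of these tests was split by distance from the start site, and shared peaks lay at promoters more often than single-context peaks. The odds ratios therefore cannot separate being shared from lying at a promoter.

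**Figure D3:**
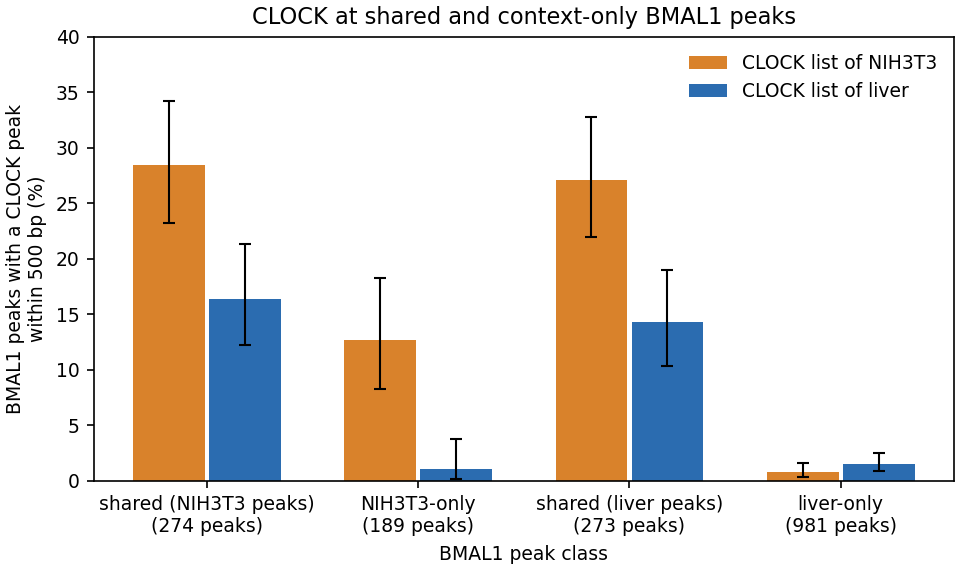
Percent of BMAL1 peaks with a CLOCK peak within 500 bp (vertical axis) for each class of BMAL1 peak (horizontal axis), with bars for the NIH3T3 (orange) and liver (blue) CLOCK lists and 95% Clopper-Pearson intervals as error bars. With the NIH3T3 CLOCK list, shared NIH3T3 peaks stand at 28.5% and NIH3T3-only peaks at 12.7%, and with the liver CLOCK list, shared liver peaks stand at 14.3% and liver-only peaks at 1.53%.

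CLOCK sites shared between the contexts stood at clock genes. For 26 of the 28 liver CLOCK peaks with an NIH3T3 CLOCK peak within 500 bp, the nearest BMAL1 peak was annotated to Per1, Per2, Cry1, Nr1d1, Nr1d2, Gm129, Dbp, Tef or Hlf, at most 3899 bp away, and for 13 of them it was annotated to Nr1d1. A BMAL1 peak lay within 500 bp for 20 of the 28, and the other 8 lay farther from any. The other 2, named after their values were seen, stood at Mthfd1l and 2410080I02Rik. At Nr1d1 the NIH3T3 list had 12 CLOCK peaks and the liver list 15 between 98633776 and 98645278 on chromosome 11. These 28 were 6.38% of the 439 liver CLOCK peaks (4.28 to 9.09), against a mean of 0.206 and a maximum of 3 after the shifts (one-sided permutation p = 0.001). In both lists most CLOCK peaks had no BMAL1 peak of the same context within 500 bp. BMAL1 stood at 80 of 1016 NIH3T3 CLOCK peaks (7.87%, 6.29 to 9.70) and at 47 of 439 liver CLOCK peaks (10.7%, 7.97 to 14.0). The share of liver CLOCK peaks with an NIH3T3 partner was 3.73%, or 14 of 375, when CLOCK peaks closer than 1 kb were joined into loci.

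**Figure D4:**
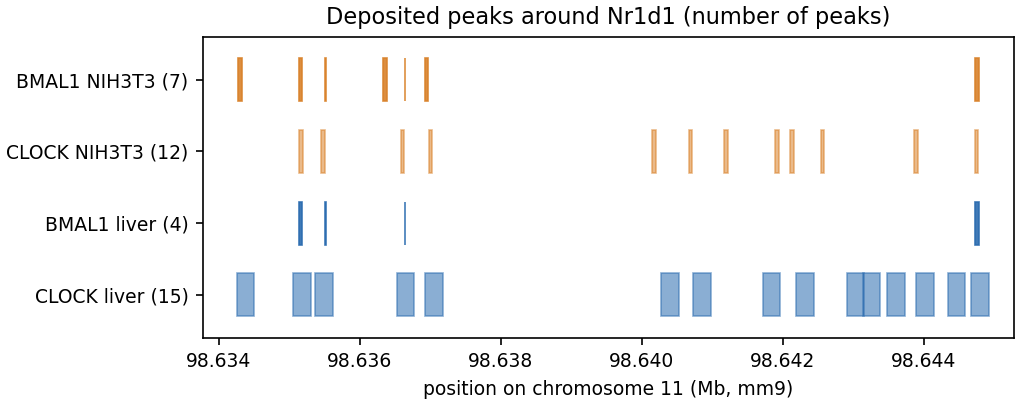
Map of the deposited peaks of the 4 lists (rows, with the number of peaks) around Nr1d1, the clock gene with most NIH3T3 BMAL1 peaks, with mm9 position on chromosome 11 in Mb on the horizontal axis and boxes drawn to scale. The BMAL1 lists hold 7 and 4 peaks, and the CLOCK lists hold 12 and 15, of which 7 in NIH3T3 cells and 8 in liver lie more than 500 bp from any BMAL1 peak.

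The last comparison was made at the level of genes. Of 345 genes annotated to an NIH3T3 BMAL1 peak, 193 (55.9%, 50.5 to 61.3) were also annotated to a liver BMAL1 peak, 152 were in NIH3T3 cells alone, and 792 were in liver alone. Core clock genes were less frequent among the liver-only genes, with 2 of 792 against 10 of 345 NIH3T3 genes, an odds ratio of 0.085 (0.00901 to 0.402; two-sided Fisher exact p = 2.12e-04, adjusted over 10 lists 0.00212). All 10 of those NIH3T3 genes were also liver genes, and against the 152 NIH3T3-only genes the count was 2 against 0 (two-sided Fisher exact p = 1). No other list passed the test. Cell cycle genes numbered 6 in NIH3T3 cells and 3 among liver-only genes (odds ratio 0.215, Fisher exact adjusted p = 0.0926). Ccne1, Ccne2 (both E cyclins), Cdk4 and Wee1 were in both contexts, Bax and Gadd45g in NIH3T3 cells alone, and Ccnd1, Max and Plk2 in liver alone. The liver peaks of Ccnd1 and Plk2 lay 116643 and 60246 bp from the start site, and that of Max lay at 9 bp. Within 10 kb of start sites the list had 5 NIH3T3 genes and 1 liver-only gene (Fisher exact adjusted p = 0.141). Stress response genes numbered 3 in NIH3T3 cells and 0 among liver-only genes (Fisher exact adjusted p = 0.0926). Of these, Cirbp (cold-inducible RNA binding) and Hspe1 (a mitochondrial chaperonin) were in NIH3T3 cells alone, and Trib1 was in both contexts at different sites.

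Metabolic genes with BMAL1 peaks were for the most part annotated in liver alone, as were most genes of the liver list overall. The lipid, cholesterol and bile acid list had 13 liver-only genes and 4 NIH3T3 genes (odds ratio 1.42, Fisher exact adjusted p = 0.989). Angptl4, Dgat2 and Elovl1 were in both contexts and Lpin2 in NIH3T3 cells alone, and the liver-only genes included Abcb4, Acsl1, Apoa5, Elovl6, Fabp1, Fads2, Plin2, Pnpla2, Pnpla3, Ppara, Slc27a2 and St3gal5. Ppara, the nuclear receptor for fatty acids, had 3 liver peaks. The glucose and insulin list had 11 liver-only genes, among them Gys2 (liver glycogen synthase), Pygl (liver glycogen phosphorylase), Slc2a2 (the GLUT2 transporter) and Pfkl, and 4 NIH3T3 genes, namely Foxo3, Pcx, Pfkfb3 and Irs2 (odds ratio 1.20, Fisher exact adjusted p = 1). The xenobiotic list had 10 liver-only genes, among them Por (the reductase that serves cytochromes P450), Gstm1, Abcc2 and Nfe2l2, and 1 NIH3T3 gene, Gclc (odds ratio 4.39, 0.621 to 191.5, Fisher exact adjusted p = 0.377).

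The hepatocyte list had 4 liver-only genes, among them Arg1, Asgr2 and Upp2, and 1 NIH3T3 gene, Krt8 (odds ratio 1.75, Fisher exact adjusted p = 1). The peaks of Arg1, Asgr2 and Krt8 lay 21129, 16636 and 19893 bp from the start site, and that of Upp2 lay at 84 bp. The fibroblast list had 1 NIH3T3 gene, Tgfb2, and 5 liver-only genes, among them Actg1, Actn1, Cyr61 and Prrx1 (odds ratio 2.18, Fisher exact adjusted p = 0.963). Within 10 kb of start sites the hepatocyte list had 1 liver-only gene and 0 NIH3T3 genes. The fibroblast list then had 2 liver-only genes and 1 NIH3T3 gene. No gene of the list for non-parenchymal and blood cells was annotated to a BMAL1 peak. The list of other transcription factors had 16 liver-only genes, among them Klf15, Esrra, Bcl6 and Irf2bp2, and 9 NIH3T3 genes (odds ratio 0.770, Fisher exact adjusted p = 0.861). Klf9, Klf11, Junb, Hif1a and Tsc22d3 had shared peaks, Hes1 was in both contexts at different sites, and Nr6a1, Rarg and Tcf7l2 were in NIH3T3 cells alone. The clock output list had 1 liver-only gene and 3 NIH3T3 genes (odds ratio 0.144, Fisher exact adjusted p = 0.215).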

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

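The tests of differences between contexts and those of the gene column and of CLOCK sites without BMAL1 were not among the comparisons chosen in advance. They were chosen after the results were seen, and only for the test of CLOCK sites common to both contexts was the prediction written before its result. The excess of CLOCK at shared over context-only BMAL1 sites differed between contexts, with an odds ratio of 10.7 in liver and 2.73 in NIH3T3 cells. With plain odds ratios and 0.5 added to each count, in place of the conditional estimates just given, the ratio of liver over NIH3T3 cells was 3.89 (95% bootstrap interval over loci 1.72 to 9.02), and without peaks of clock genes such as Nr1d1 and Dbp it was 2.28 with an interval that included 1 (0.681 to 6.44). The excess of promoter peaks at shared over context-only BMAL1 sites also differed, with a ratio of odds ratios of 2.36 (1.68 to 3.31) for liver over NIH3T3 cells, and of 2.38 (1.69 to 3.35) without clock genes. The promoter share of shared peaks was nearly the same in both lists, at 83.9% and 84.2%, as most shared peaks were the same entries in both. This ratio therefore largely restates the odds ratio of 2.31 between NIH3T3-only and liver-only peaks and is not a separate difference. Both context-only classes also depend on the unknown thresholds of the lists, and the ratio for CLOCK was not adjusted for the promoter share.

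A signal outside the comparisons came from the gene column of the NIH3T3 CLOCK list. Of 670 peaks whose gene could be checked, 574 (85.7%, 82.8 to 88.2) carried the name of a gene on another chromosome. Older gene symbols that point to other genes are excluded as the main cause, since 0 of 1122 checked peaks of the liver BMAL1 list and 0 of 437 of the NIH3T3 BMAL1 list had such a name. Names displaced from their coordinates within the list are a candidate explanation. For 67 of 79 CLOCK peaks at a BMAL1 peak with a gene (84.8%), that gene stood within 30 rows in the CLOCK gene column, against at most 18 after 1000 shuffles of the column, and it stood on the same row for 33. No biological explanation was tested for this pattern.

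Most CLOCK peaks had no BMAL1 peak of their own context within 500 bp, 936 of 1016 (92.1%, 90.3 to 93.7) in NIH3T3 cells and 392 of 439 (89.3%, 86.0 to 92.0) in liver. Of those in NIH3T3 cells, 5 of 936 (0.534%, upper limit 1.24) lay at liver BMAL1 peaks. This does not decide whether they were BMAL1 sites that missed the threshold in NIH3T3 cells, because peaks picked for lacking NIH3T3 BMAL1 cannot be measured against the sites shared by both BMAL1 lists. CLOCK peaks without BMAL1 were seldom common to both CLOCK lists. Of liver CLOCK peaks with no BMAL1 peak in either list, 8 of 391 (2.05%, 0.887 to 3.99) lay at NIH3T3 CLOCK peaks. Of those with a BMAL1 peak, 20 of 48 (41.7%, 27.6 to 56.8) did. Common sites too weak to be called in NIH3T3 cells would be missed, because depth is unknown, so this does not decide whether such sites exist. Lower-placed entries of the NIH3T3 CLOCK list may account for part of the pattern, since the share with BMAL1 was 53.0% (42.8 to 63.1) in the first 100 entries and 2.95% (1.95 to 4.26) in the other 916, although what orders that list is not stated. BMAL1 sites below the threshold, CLOCK binding without BMAL1, whether particular to a context or common but uncalled, and weaker sites of any kind stay open. The lists were also not matched for time. The liver BMAL1 libraries were taken at zeitgeber time 6, and no time was given for the liver CLOCK sample. In NIH3T3 cells the BMAL1 list was named for 20 h, while the CLOCK libraries spanned 18 to 38 h. Differences in time therefore stay open too.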

How the results depend on the processing

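All 24 alternative values of the 4 odds ratios kept their direction and their side of the Fisher exact threshold. The 21 alternatives of the 4 overlaps all gave the smallest permutation p, which cannot show a weaker overlap, so only their shares were read. The shared share of NIH3T3 BMAL1 peaks ranged from 52.8% to 60.5%, that of liver CLOCK peaks from 3.73% to 7.06%, and CLOCK at BMAL1 peaks from 12.5% to 22.7% in NIH3T3 cells and from 2.23% to 4.31% in liver. The odds ratios ranged from 3.96 to 10.5 and from 1.76 to 2.88 for CLOCK at shared against liver-only and NIH3T3-only peaks. Those for promoters ranged from 5.18 to 11.8 in liver and from 2.02 to 4.94 in NIH3T3 cells. The lowest CLOCK odds ratios came from leaving out the clock genes, and those for promoters from the 200 bp window. Genes in both contexts, a count with no test, numbered 176 instead of 193 within 10 kb of start sites. The outcome changed for the number of gene lists past the threshold, which was 1 in the main comparison and 0 with liver-only set against NIH3T3-only genes (3 and 1 at an unadjusted p under 0.05), because the latter leave out the shared genes and number 152. In that setting the difference in percentage points, liver-only minus NIH3T3-only, also changed sign to 0.253 for core clock genes, 0.126 for clock output genes, -0.0266 for fibroblast genes, -0.153 for hepatocyte genes and 0.0465 for other transcription factors, each with a Fisher exact adjusted p of 1. Joined peaks, left-out clock genes and identical intervals were alternatives chosen after seeing the data. No paired analysis was possible because the peak lists carried no values per library, and leaving out replicates and a stricter selection by score were not run for the same reason and for lack of scores. Depth is unknown, so an absent peak was not read as absent binding.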

Other observations

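The tests below were chosen after the results were seen. For the follow-up test on ribosome biogenesis genes with promoter peaks, only the prediction was written before its result. Sites with both proteins in both contexts were mostly clock sites. Of 191 shared BMAL1 loci (peaks within 1 kb joined), 13 had CLOCK in both contexts, 36 in NIH3T3 cells alone, 9 in liver alone and 133 in neither. The 30 peaks with both proteins in both contexts were annotated to 11 genes, of which 9 were Per1, Per2, Cry1, Nr1d1, Nr1d2, Gm129, Dbp, Tef and Hlf. The other 2, named after the values were seen, were Mthfd1l (chromosome 10, 6372752 to 6372801, 606 bp from the start site) and 2410080I02Rik (chromosome 19, 23210227 to 23210276, 861 bp). Clock genes held 11 of the 13 loci and 8 of the other 178 shared loci, an odds ratio of 107.4 (19.3 to 1153; two-sided Fisher exact p = 2.35e-11). The clock lists were fixed in advance, but the test was prompted by the names above, so its p restates that observation and is not separate evidence for it.

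CLOCK peaks that both contexts had in common and that had no BMAL1 peak within 500 bp lay almost all at Nr1d1. Of the 8 such liver CLOCK peaks, 7 lay at Nr1d1, from 98640280 to 98644141 on chromosome 11, between the BMAL1 peaks near the start site and the BMAL1 peak at 98644729 to 98644778. Their centres lay 737 to 3899 bp from the nearest BMAL1 peak. These 7 stood close together at a single locus, so they are not 7 independent sites. The remaining peak lay at chromosome 7, 52963582 to 52963831, with its centre 560 bp from the nearest BMAL1 peak, which was annotated to Dbp. Within 10 genes BMAL1 had peaks in both contexts with no shared site. Hes1, a Notch target, had its nearest NIH3T3 peak at 34 bp and its liver peak at 18659 bp from the start site. Trib1, a pseudokinase gene, had them at 79831 bp and 4283 bp. P2ry2 and Fkbp11, named after their values were seen, had them at 21410 and 7 bp and at 585 and 73 bp.

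Shared BMAL1 loci held several peaks more often than loci of a single context. In liver 61 of 191 shared loci (31.9%) and 53 of 925 liver-only loci (5.73%) held more than 1 peak, and in NIH3T3 cells 63 of 190 (33.2%) and 15 of 172 (8.72%) did, each locus being classed by its first peak. The highest two-sided Fisher exact p over both lists, with and without clock genes, was 4.02e-07. As most shared peaks were the same entries in both lists, the lists do not give independent results. Srm, which encodes spermidine synthase and was named after its values were seen, had 6 peaks in each list, and 4 of the 8 genes with 4 or more peaks in either list were clock genes. These counts are per gene and not per locus. Peaks of a gene can lie far apart, as for Irf2bp2, with liver peaks at 3084 to 142540 bp from the start site. Strong enrichment may make a caller report several peaks, which the lists cannot show without scores.

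Genes of ribosome biogenesis, a list chosen after the gene names were seen, numbered 8 of 345 NIH3T3 BMAL1 genes and 4 of 792 liver-only genes. The odds ratio was 4.67 (1.24 to 21.3; two-sided Fisher exact p = 0.00987), but a test on genes chosen from the same lists does not show that they differ. In NIH3T3 cells alone they were Bop1, Nat10, Npm1, Rbm19, Rrn3 and Utp3, in both contexts Ncl and Utp18, and in liver alone Gnl3, Polr1b, Taf1c and Utp11l. The peak of Nat10, at chromosome 2, 103601319 to 103601378 and 4 bp from the start site, also had an NIH3T3 CLOCK peak, and the shared peak of Ncl, at chromosome 1, 88255344 to 88255423, had a liver CLOCK peak and no NIH3T3 one. Among genes with a promoter peak the odds ratio was 3.25 with an interval that included 1 (0.770 to 19.2), so the larger share of promoter peaks in NIH3T3 cells was not excluded either.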
